A study of Danio rerio with 84 samples.

How the data were processed

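Transcript levels were measured in pooled whole zebrafish embryos exposed to cadmium, cobalt or copper, with 1 one-colour Agilent zebrafish array per sample and 84 arrays in all. Per the labels, embryos were kept 1 per well in metal solutions made in diluted ISO standard water, collected at 48 or 96 hours post fertilization (hpf), pooled and frozen before RNA extraction. The labels give 3 concentrations per metal (C1 to C3) and a water control (C0) for each metal and stage, with 3 replicates per group at 48 hpf and 4 at 96 hpf. The labels do not say whether replicates came from separate spawnings. The p-values therefore measure the spread between samples.

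Per the file headers, the deposited processed signal was an intensity that Agilent Feature Extraction 9.5.1.1 had background-subtracted and detrended within each array, with an offset from the negative controls and surrogate values for dim spots. No normalization between arrays is recorded in those headers. The mean spot signal and the local background median were deposited as raw intensity, per the file headers, and the flags for outlier spots and for spots well above background are Feature Extraction's own, per the file headers. The slide of replicate 2 in the cadmium 96 hpf set had been extracted with an older protocol version than the others, per the file headers. Its multiplier for calling a spot well above background was 2.6, against 13 on the other arrays. On its arrays 2239 to 5193 spots kept a processed signal of 0 or below, against 0 on the others. Those spots took the floor value described next. The deposited series matrix intensity values were used as an alternative source.

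Each processed signal was divided by the array's percentile 75, floored at 0.01 of that percentile and put on a log2 scale. Control spots and spots with an outlier flag were left out, and spots of 1 probe were averaged. Of the 43603 probes, 28697 were named through their accession and 5125 through their symbol in the supplied names table (assembly GRCz12tu, used for names only). An older symbol named 762 more, 3464 kept the name in the file and 5555 stayed unnamed. A gene was represented by its probe with the highest mean over all 84 arrays, which gave 20805 named genes, and unnamed probes stood for themselves. A feature was tested when it was well above background on at least 3 arrays of a set at 48 hpf or 4 arrays at 96 hpf. Coordinates are those of the probes in the files, in build danRer7. The number of arrays limits the precision.

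Each metal and stage was fitted on its own in R 4.3.3 with limma 3.58.1 (statmod 1.5.0, and version 1.17.8 of data.table), with 1 mean per concentration group and a shared spread. Limma's moderated test compared C1, C2 and C3 with C0 and tested a linear trend with concentration. The C3 response at 96 hpf was tested against that at 48 hpf in a fit of both stages. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all features tested. A feature not well above background on any array of the dimmer group has only a bound. For it the brighter group's mean was set against the higher of the feature's own level and the lowest level among features well above background, as at least N-fold. For 19 sentinel genes of metal and stress responses, the C3 responses were compared between metals with adjustment over that family.

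The gene lists were 32 in number: metallothionein and zinc transport, copper handling, iron handling, heat shock and protein folding, Nrf2 and glutathione response, hypoxia response, glycolysis, unfolded protein response, p53 and apoptosis, inflammation and acute phase, macrophages and neutrophils, globins and red cells, skeletal muscle, heart muscle, neurons and synapses, glia and myelin, photoreceptors, lens, liver, exocrine pancreas and gut, aryl hydrocarbon receptor and drug metabolism, hair cells and lateral line, ionocytes and ion regulation, skeleton and extracellular matrix, pigment cells, keratins and epidermis, hatching gland, cell cycle, cholesterol synthesis, proteasome, circadian clock, and glucocorticoid response. Each was tested at C3 against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the 192 tests of 6 sets. A list can therefore rank above the other genes while its mean is near 0. Markers of cell types are expressed in whole embryos throughout, and some genes stand in more than 1 list. A count adjusted over the list alone uses only the members of that list.

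Genes were named by a rule. It took up to 8 called genes with the largest rise and up to 8 with the largest fall at C3, among named genes whose groups did not overlap and that were well above background in the brighter group. It added up to 3 called members of each list, the sentinel genes, up to 4 rises and 4 falls at C1 and at C2, up to 5 per direction for the difference between stages, and up to 10 shared by all metals. Where C3 called fewer than 5 named genes, the 5 with the smallest p were taken. The lists, the rule, the comparisons, the tests and the alternatives were fixed before the data were examined, except where a later choice is named.

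Per the file headers, the replicate number, the slide and the scan day coincide within a set: each slide holds C0 to C3 of 1 replicate, always in the same positions. Arrays of 1 slide deviated together from their group means. The median correlation of these deviations was 0.518 and 0.649 for cadmium at 48 and 96 hpf, 0.488 and 0.555 for cobalt, and 0.438 and 0.691 for copper, and the lowest single value was 0.077. The fit without a slide block is the main one, and values with the slide as a block stand beside it where they differ in the call.

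The code was tested on simulated data with known changes. Each gene had its real mean and slide means, plus normal noise with the spread of the fit with a slide block. The data thus followed the blocked model, without single outlying arrays, so recovery and false calls in real data may differ. Without a block, 91.9% of genes changed 4-fold were recovered for cadmium at 48 hpf, 70% for cadmium at 96 hpf, 26.6% for cobalt at 48 hpf, 60.5% for cobalt at 96 hpf, 67.1% for copper at 48 hpf and 80.6% for copper at 96 hpf. For 2-fold changes the recovery was 32.4%, 5.5%, 0%, 7.4%, 14.1% and 18.2% in that order. With the slide as a block, recovery of 2-fold changes was 85.3%, 64.4%, 6.7%, 52.9%, 54.9% and 74.2% in that order. The block also called 9, 6, 4, 7, 8 and 7 unchanged genes, 4.58% to 7.69% of its calls, against 0, 0, 1, 0, 0 and 0 without it.

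The alternatives were normexp background correction (offset 50) of the raw signals, quantile normalization, no filter, the mean of all probes of a gene, the series matrix values, a fit of only the groups compared, the replicate or slide as a block, weights by concentration rank, each array left out in turn, an estimated correlation in camera, and limma's fry. Fits without control replicate 3 of cadmium at 96 hpf, and without 1 array of each cobalt set together with the slide block, were chosen after seeing the data, as were the list tests that join the block with an estimated correlation or with fry. The same rule for named genes was then applied to the blocked fit and to the fit without that control, also after seeing the data. Control spots and the sentinel gene cdkn1a, which is not on the array, were left out. No array was left out of the main fits.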

Results

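The arrays measured transcripts of whole zebrafish embryos at 48 and 96 hpf after exposure to cadmium at 0.9, 1.8 and 3.3 mg/L, cobalt at 0.5, 1.4 and 3.6 mg/L, or copper at 1.7, 2.5 and 6.1 µg/L, called C1, C2 and C3 for each metal. Each metal and stage had its own water controls, so that 24 groups of 3 arrays (48 hpf) or 4 arrays (96 hpf) were compared. The series title puts the question as one of dependence on concentration. The concentrations differ between metals, so equal levels are not equal doses. The percentile 75 of the signal, used for scaling, ran from 57.2 on the dimmest array (cobalt 48 hpf, C1 replicate 2) to 1081 on the brightest (copper 96 hpf, C2 replicate 3). Arrays of 1 group correlated with a median r of 0.975 across probes, and arrays of different stages never above 0.945. All values below are log2 changes from the control with standard errors (SE), and adjusted p-values come from limma's moderated test.

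**Figure D1:**
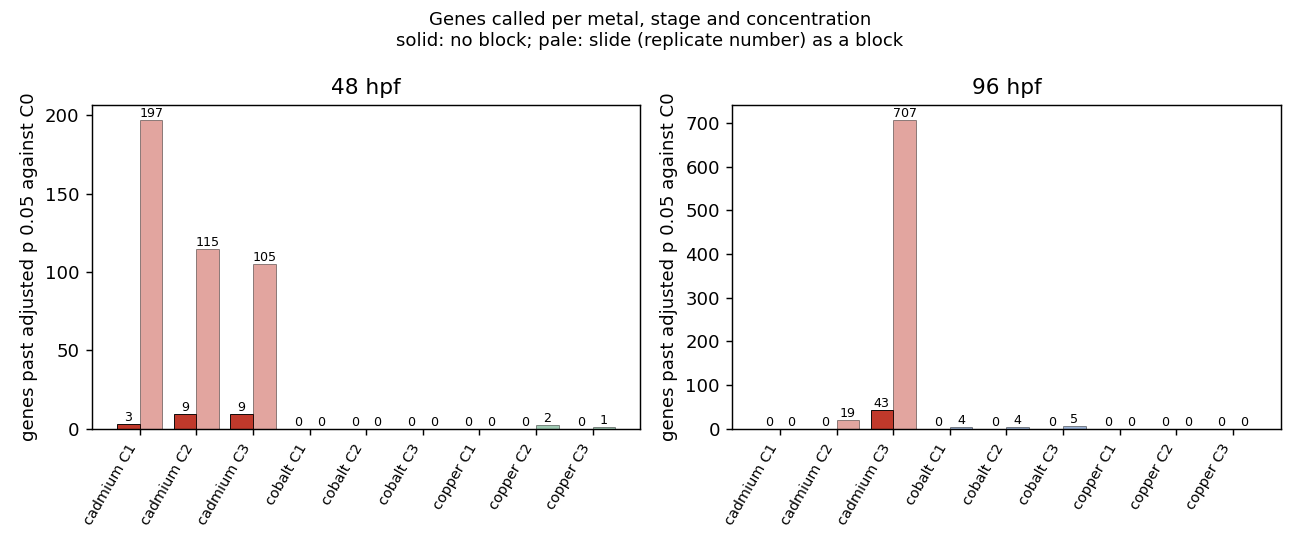
Number of genes called against the control (vertical axis, count) at C1, C2 and C3 of each metal (horizontal axis), at 48 and 96 hpf; solid bars are fits without a block and pale bars fits with the slide as a block. The tallest bars are cadmium at 96 hpf, C3, with 43 genes without and 707 with the block.

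At 48 hpf cadmium lowered stc1l and trpv6 and raised 3 heat shock genes. stc1l, which encodes a stanniocalcin, the hormone family that limits calcium uptake in fish, fell by 3.19 ± 0.30 on the log2 scale at 3.3 mg/L (SE, n = 3 against 3, 9.14-fold, adjusted p = 0.00331), from a mean of −2.67 ± 0.26 (SD) to −5.86 ± 0.68 relative to the array's percentile 75. That C3 mean lay below the lowest level well above background on each C3 array (−5.85, −5.32 and −5.2). The size of the stc1l fall is therefore uncertain. trpv6, the epithelial calcium channel, was at least 2.01-fold lower (adjusted p = 0.000636), since no C3 array measured it well above background. The heat shock genes hsp70l (1.72 ± 0.22, 3.3-fold, adjusted p = 0.0284), hsp70 (1.70 ± 0.17, adjusted p = 0.00615) and hsp70.3 (1.61 ± 0.19, adjusted p = 0.015) rose. Each of these changes ran the same way on all 3 slides. The stc1l probe lies on chromosome 10 at 44043774 to 44043833 on the minus strand, the trpv6 probe on chromosome 16 at 14044375 to 14044432 on the minus strand, and the hsp70l probe on chromosome 8 at 5009274 to 5009334 on the plus strand, in build danRer7.

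At C3, 9 genes were called, 4 higher and 5 lower. The others were LOC571582 (1.43 ± 0.13, adjusted p = 0.00331), ora3.1, an olfactory receptor (−1.22 ± 0.14, adjusted p = 0.0108), wfikkn2b, a secreted protease inhibitor (at least 1.77-fold lower, adjusted p = 0.0321), and the unnamed probe A_15_P400660 (at least 2.25-fold lower, adjusted p = 0.00615). Both calcium genes were already lower at 0.9 mg/L, where 3 genes were called. stc1l fell by 2.94 ± 0.30 (adjusted p = 0.0113), trpv6 was at least 2.81-fold lower (adjusted p = 0.00108) and LOC571582 rose by 1.09 (adjusted p = 0.0354). At 1.8 mg/L 9 genes were called, 4 higher and 5 lower. stc1l was at least 8.1-fold lower (adjusted p = 0.00412), trpv6 at least 2.55-fold lower (adjusted p = 0.000875), wfikkn2b at least 2.24-fold lower (adjusted p = 0.0234), and si:rp71-36a1.3 at least 5.93-fold higher (adjusted p = 0.000414). ora3.1 fell by 1.19 (adjusted p = 0.0161) and A_15_P400660 by 1.72 (0.0398), while hsp70 rose by 1.29 (0.0398), LOC571582 by 1.16 (0.0136) and A_15_P113609 at least 1.37-fold (0.0234). A linear trend with concentration was called for 8 genes, 4 in each direction. After normexp background correction of the raw signals no gene was called at any level or for the trend, and LOC571582 had the opposite sign at C2 (−0.17) and C3 (−0.24), as did A_15_P113609 at C2 (−0.31). A fit of only the groups compared called 1, 1 and 0 genes at C1, C2 and C3, and without the filter on dim probes C1 had 5.

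With the slide as a block the counts at 48 hpf were 197 genes at C1 (144 higher, 53 lower), 115 at C2 (71 and 44) and 105 at C3 (67 and 38), and 62 for the trend. By the same rule for naming, applied after the data were seen, the C3 genes then called included and3, which encodes a fin fold fibre protein (2.21, adjusted p = 0.037 with the block and 0.319 without), and the immediate-early genes fosab (1.69, 0.0262 and 0.292), egr4 (1.35, 0.0291 and 0.0568) and npas4a (1.24, 0.0223 and 0.155). tnfb, a tumour necrosis factor, was higher by 1.43 (0.0238 and 0.133), and fthl28, a ferritin heavy chain gene, by 1.23 (0.0186 and 1). s100a11, a calcium-binding protein, had a change of −2.3 (0.000827 and 0.0801), and ca15a, a carbonic anhydrase of acid-secreting ionocytes, had a change of −1.38 (0.00161 and 0.0639). hsp90aa1.2 (1.03, 0.00295 and 0.534), gsto2 (1.13, 0.0198 and 0.386) and sqstm1, the autophagy receptor p62 (0.66, 0.0328 and 0.298), were also called. Of the other sentinel genes, mt2, a metallothionein, had a change of 1.03 ± 0.26 (adjusted p = 0.525, blocked 0.0611), the collagenase gene mmp9 1.99 ± 0.46 (0.398 and 0.0819), and hmox1a, heme oxygenase, 0.11 ± 0.20 (1 and 0.683).

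In the 46 tested genes of inflammation and acute phase the mean change at C3 was 0.33, and the list ranked above the other genes (adjusted p = 1.5e-11; adjusted p = 0.0651 with an estimated correlation). None of its members passed over all genes, 8 rose adjusted over the list alone, and 3 with the block. Keratins and epidermis had a mean of 0.33 over 45 genes (adjusted p = 6.36e-23; adjusted p = 0.0744 with an estimated correlation), with 0 calls over all genes, 5 adjusted over the list alone and 4 with the block. Macrophages and neutrophils (mean 0.31, adjusted p = 9.77e-10), aryl hydrocarbon receptor and drug metabolism (0.21, 3.95e-05), Nrf2 and glutathione response (0.14, 2.99e-06), iron handling (0.14, 0.00377), p53 and apoptosis (0.13, 0.000458), skeleton and extracellular matrix (0.13, 2.56e-05), skeletal muscle (0.11, 3.97e-06), heart muscle (0.14, 0.0429) and globins and red cells (0.07, 0.0162) also ranked higher. With an estimated correlation their adjusted p-values were 0.137, 0.093, 0.156, 0.0842, 0.144, 0.465, 0.465, 0.624 and 0.49 in that order. The heat shock list did not pass (adjusted p = 0.0504), with 2 of 32 members called higher, 3 higher and 1 lower adjusted over the list alone, a mean of 0.11 and a median of −0.07. The ionocyte list did not pass either (adjusted p = 0.224), with 2 of 46 members called lower, and 1 higher and 4 lower adjusted over the list alone. Metallothionein and zinc transport had an adjusted p of 0.0555. Signs also differed between mean or median and test for copper handling, unfolded protein response, glia, hair cells, pigment cells, cholesterol synthesis and glucocorticoid response, none of which passed.

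The cadmium 48 hpf calls held to different degrees when 1 array was left out. At C3, stc1l, trpv6 and LOC571582 were called whichever array was left out, whereas hsp70l and wfikkn2b missed the threshold without any 1 of the 6 (adjusted p up to 0.176 and 0.225). hsp70 missed it without control replicate 2 (0.0526), hsp70.3 without control replicate 1 or 2 or C3 replicate 2 or 3 (0.0579 to 0.108), ora3.1 without control replicate 1 or 2 or C3 replicate 3 (0.0678 to 0.0891) and A_15_P400660 without control replicate 1 (0.0531). and3 was called without C3 replicate 2 (2.75, adjusted p = 0.0378). The count at C3 was 4 without control replicate 1 or 2 and 5 without C3 replicate 3. The count at C1 was 1 without control replicate 2 or C1 replicate 1 or 2. At C2 it was 3 without control replicate 2 or C2 replicate 3, 4 without control replicate 1 or 3, and 5 without C2 replicate 1 or 2. At C1 the call of LOC571582 was lost without each array except control replicate 3 (adjusted p up to 0.333), and that of stc1l without control replicate 2 or 3 or C1 replicate 1 or 2 (0.064 to 0.115). At C2 hsp70, A_15_P400660 and A_15_P113609 lost theirs without each array (up to 0.255, 0.234 and 0.139), wfikkn2b without each except control replicate 1 (up to 0.136), ora3.1 without each except C2 replicate 1 (up to 0.122) and LOC571582 without each except control replicate 3 (up to 0.122). The trend count was 3 without control replicate 2 and 5 without control replicate 1 or C3 replicate 3. The lists of globins (up to 0.187) and heart muscle (up to 0.272) lost their calls without control replicate 1 and both C3 replicates 1 and 3, globins also without control replicate 3 and heart muscle without control replicate 2. Heat shock (0.0311 without control replicate 3), metallothionein (0.0122 without control replicate 1), ionocytes (0.0344 without C3 replicate 1) and neurons (0.0202 without C3 replicate 2) gained one.

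At 96 hpf cadmium at 3.3 mg/L raised mmp9, mmp13a, hmox1a, hsp70l and slc30a1a among others. mmp9 (4.26 ± 0.62, SE, n = 4 against 4, 19.1-fold, adjusted p = 0.0112) and mmp13a (3.97 ± 0.72, 15.7-fold, adjusted p = 0.0388), encode matrix metalloproteinases. hmox1a, of heme breakdown, rose by 3.38 ± 0.44 (10.4-fold, adjusted p = 0.00429), from −2.50 ± 1.22 (SD) in controls to 0.88 ± 0.30. hsp70l rose by 2.50 ± 0.30 (5.66-fold, adjusted p = 0.00283) and the zinc exporter gene slc30a1a by 1.24 ± 0.20 (2.36-fold, adjusted p = 0.0197). In all, 43 genes were called at C3, 41 higher and 2 lower, and 44 for the trend with concentration, 42 and 2. After normexp correction the counts were 0 and 3, in a fit of only C3 and C0 1 gene was called, and without the filter on dim probes 28 were. The mmp9 probe lies on chromosome 8 at 25148717 to 25148776 on the plus strand, and the hmox1a probe spans 27021597 to 27023156 on chromosome 3, plus strand, in danRer7.

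Further genes that rose at C3 were calml4b, a calmodulin-like gene (at least 4.76-fold, adjusted p = 0.00532), pir, encoding the iron-binding protein pirin (2.94 ± 0.40, 0.00623), smtlb, the pituitary hormone somatolactin beta (2.82 ± 0.46, 0.0201), gsto2, a glutathione transferase (2.74 ± 0.50, 0.0391), and stat1b of interferon signalling (2.64 ± 0.44, 0.0253). The chaperone hsp70.3 (2.59 ± 0.38, 0.012), the ferritin genes fthl31 (2.00 ± 0.30, 0.0133) and fthl29 (1.92 ± 0.35, 0.0391), sqstm1 (1.64 ± 0.29, n = 3 against 4, 0.0391) and the anion exchanger slc4a2a (1.33 ± 0.24, 0.0335) rose too. At 0.9 and 1.8 mg/L limma called 0 genes, while 228 and 533 had an unadjusted p under 0.05.

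Control replicate 3 of this set lay with the exposed arrays. Its hmox1a level was −0.67 and its fthl28 level 4.29, against at most 0.89 for fthl28 in the other controls. A score, the mean signed log2 difference from the other 3 controls over 64 genes called at C3 on the other slides, was 1.85 for that array, against −0.20 to 0.16 in the other 3 controls. In fits without it, chosen after the data were seen, 128 genes were called at C3 (121 higher, 7 lower), 71 at C2 (66 and 5), 18 at C1 (16 and 2) and 136 for the trend. All 43 genes called at C3 with every control were called again in the same direction. Dropping a control like the exposed arrays favours calls at each level, so this is no separate test. With n = 3 against 4, mmp9 rose by 5.03 ± 0.42 (32.8-fold, adjusted p = 3.38e-05), fthl28 by 4.19 ± 0.44 (18.2-fold, 0.000286), hmox1a by 3.99 ± 0.24 (15.9-fold, 2.64e-06), mt2 by 2.97 ± 0.52 (7.84-fold, 0.0156) and hsp70l by 2.89 ± 0.19 (7.43-fold, 2.64e-06). stc1l fell by 4.08 ± 0.59 on the log2 scale (16.9-fold, 0.00395), and the calcium-buffering parvalbumin genes pvalb5 (−2.05 ± 0.34, 0.0104) and pvalb8 (−2.05 ± 0.24, 0.000746) and the corneal proteoglycan gene kera (−1.05 ± 0.20, 0.0332) fell as well. mpeg1.2, a macrophage perforin, rose by 1.81 ± 0.25 (0.00312), cebpb by 2.01 ± 0.40 (0.0396), and npsn, a neutrophil protease, by 1.81 (0.0136).

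Without that control the response was also called below the top concentration. At 1.8 mg/L fthl28 (3.79 ± 0.44, adjusted p = 0.0011), mmp9 (3.53 ± 0.42, 0.00113), hmox1a (3.1 ± 0.24, 4.51e-05), hsp70l (2.23 ± 0.19, 7.81e-05) and mt2 (2.68, 0.0446) rose, and stc1l (−4.01, 0.00711) and pvalb8 (−1.56, 0.0109) fell. At 0.9 mg/L fthl28 (3.68 ± 0.44, 0.00502), hmox1a (1.66, 0.0112), hsp70l (1.27, 0.0119) and the enamel and bone matrix genes enam (2.18 ± 0.21, 0.000817) and scpp5 (2.16 ± 0.30, 0.00795) rose, and stc1l fell by 4.33 ± 0.59 on the log2 scale (0.00795). mt2 had a change of 1.84 there (0.881, and 0.00699 with the block). At C3 il1b was at least 4.17-fold higher (0.135, blocked 0.0354), and hamp, encoding the iron hormone hepcidin, had a change of 2.61 (0.135, blocked 0.0122).

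**Figure D2:**
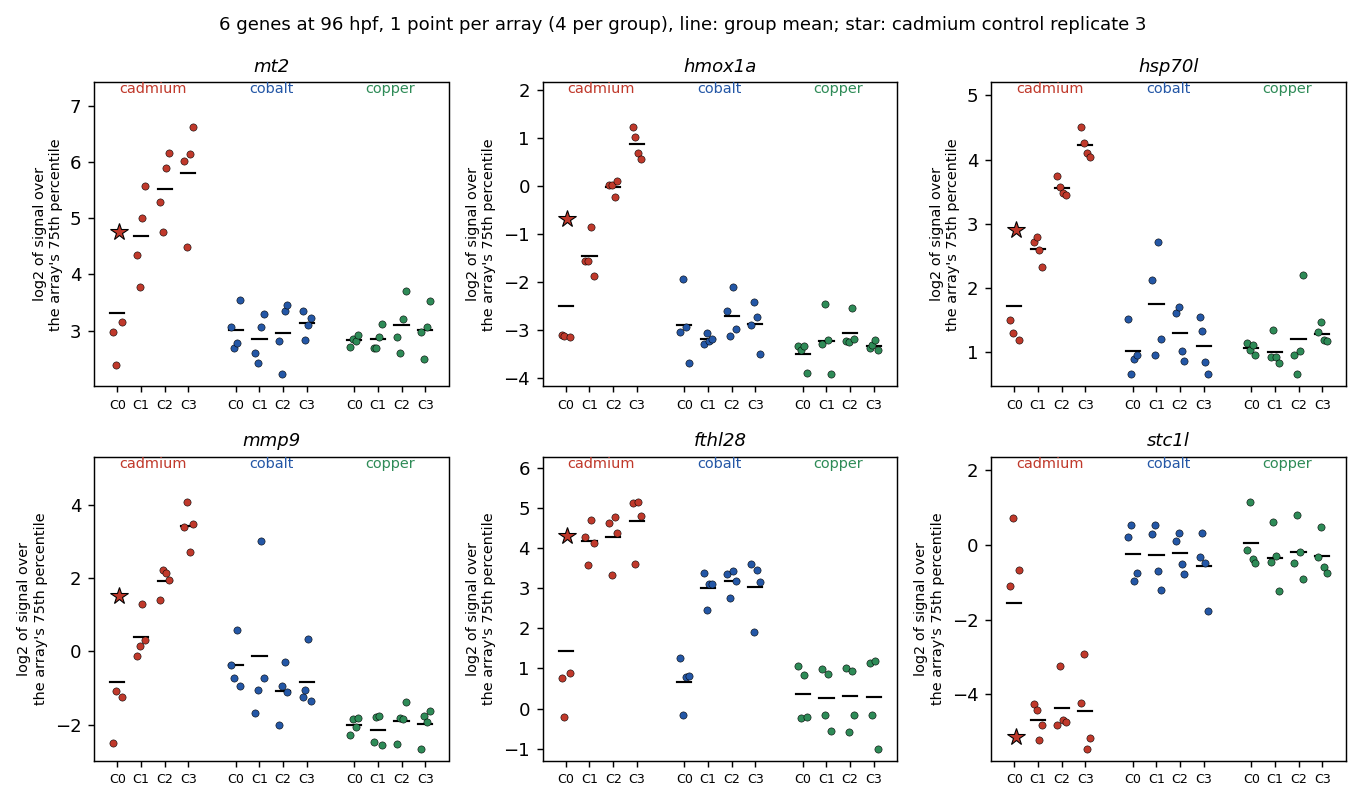
Signal of mt2, hmox1a, hsp70l, mmp9, fthl28 and stc1l at 96 hpf (vertical axes, log2 relative to the array's percentile 75) by concentration group of each metal (horizontal axes), with 1 point per array, a line at the group mean and a star for control replicate 3 of cadmium. hmox1a averaged −2.50 in cadmium controls and 0.88 at C3, and the star lies among the exposed arrays at −0.67.

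With the slide as a block and all controls kept, 0 genes were called at C1, 19 at C2 (18 higher, 1 lower), 707 at C3 (453 and 254) and 839 for the trend. With the block and without control replicate 3 the counts were 89, 458, 1066 and 1185. Genes called at C3 with all controls only with the block included mt2 (2.49 ± 0.30 with the block, 5.62-fold, adjusted p = 0.00239, and 0.127 without), fthl28 (3.24 ± 0.50, 0.00844 and 0.128), stc1l (−2.88 ± 0.68, 0.046 and 0.656), pvalb8 (−1.68 ± 0.30, 0.0163 and 0.0527) and pvalb5 (−1.75, 0.00239 and 0.0741). They also included hmox1b (2.23, 0.00316 and 0.194), hsp90aa1.2 (1.33, 0.00088 and 0.0982), the macrophage receptor marco (1.05, 0.00186 and 0.0995) and kera (−0.92, 0.0104 and 0.11). At C2 the blocked calls included pir (2.13, 0.0282 and 0.262), mt2 (2.2, 0.0282 and 0.689), hsp70l (1.84, 0.0412 and 0.146) and pvalb5 (−1.42, 0.0412). The sentinels il1b (2.31, 0.083), fosl1a (2.67, 0.0776) and hamp (1.79, 0.0883) stayed above the threshold with the block at C3, as did gclm (0.54), egln3 (−0.08), ldha (0.14), slc31a1 (−0.05), ddit3 (0.07) and cyp1a (0.30).

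Over the 6 sets, 58 of the 192 list tests passed with the preset correlation, 8 with an estimated one and 0 with an estimated one in the blocked fit. Of the 32 lists, 5 passed the first 2 ways at cadmium 96 hpf. In the blocked fit with an estimated correlation, chosen after seeing the data, their adjusted p was 0.115 for heat shock and protein folding and 0.105 for the other 4. Nrf2 and glutathione response had a mean change of 0.61 over 51 genes (adjusted p = 1.04e-16, estimated 0.0448). In it 3 genes were called higher, 14 adjusted over the list alone and 17 with the block, among them hmox1a, gsto2 and sqstm1. Without control replicate 3 these counts were 10, 15 and 20. Iron handling had a mean of 0.55 over 20 genes (1.11e-05, estimated 0.0247), with 2 called higher (fthl31 and fthl29), 3 adjusted over the list alone and 4 with the block. Heat shock and protein folding had a mean of 0.32 over 32 genes (0.000189, estimated 0.0247), with 2 called higher (hsp70l and hsp70.3), 3 adjusted over the list alone and 4 with the block. Macrophages and neutrophils had a mean of 0.65 over 30 genes (1.97e-13, estimated 0.0449), with 2 called, 5 adjusted over the list alone and 8 with the block. Without control replicate 3 the counts of this list were 3, 10 and 13. Cell cycle ranked lower, with a mean of −0.26 over 62 genes (3.41e-07, estimated 0.0247). Its members had 0 calls over all genes and 0 adjusted over the list alone, and 7 were lower with the block, such as ccne2 (−0.58, 0.0294) and plk4 (−0.44, 0.0281).

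Inflammation and acute phase had the highest mean, 0.89 over 47 genes (adjusted p = 6.36e-23, estimated 0.0651). In it 2 were called, 8 adjusted over the list alone and 11 with the block. Glucocorticoid response had a mean of 0.43 over 30 genes (4.16e-08, estimated 0.093). In it 0 were called, 3 adjusted over the list alone and 7 with the block. Its counts without control replicate 3 were 3, 5 and 13. Ionocytes and ion regulation ranked higher (mean 0.16, median 0.05, adjusted p = 0.00165, estimated 0.127). In it 1 of 47 was called, slc4a2a, and 3 adjusted over the list alone. With the block 8 were higher and 2 lower. Liver (0.28, 1.78e-05), p53 and apoptosis (0.24, 0.000189), heart muscle (0.24, 0.000169), keratins and epidermis (0.21, 0.000251), aryl hydrocarbon receptor and drug metabolism (0.18, 0.000878), glycolysis (0.16, 0.0209), skeleton and extracellular matrix (0.16, 0.0191) and unfolded protein response (0.12, 0.0222) also ranked higher, and neurons and synapses lower (−0.18, 0.00338), which turned after normexp correction (0.665). Their adjusted p with an estimated correlation was 0.543, 0.0825, 0.227, 0.366, 0.205, 0.323, 0.49, 0.289 and 0.465 in that order. Metallothionein and zinc transport did not pass (adjusted p = 0.276, mean 0.14, median −0.03), with 1 of 21 members called and 2 adjusted over the list alone. Hypoxia response (0.0545, blocked 0.00751), circadian clock (0.167, blocked 0.0353), hair cells (0.682), pigment cells (0.186), copper handling (0.426), proteasome (0.91), glia (0.44), photoreceptors (0.826) and cholesterol synthesis (0.296) did not pass without the block. Without control replicate 3, inflammation passed with an estimated correlation as well (adjusted p = 0.0174), with 5 members called and 25 adjusted over the list alone. The liver mean was then 0.47. Median and test differed in sign for copper handling, pancreas and gut, hair cells, hatching gland, proteasome and skeletal muscle, none of which passed.

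**Figure D3:**
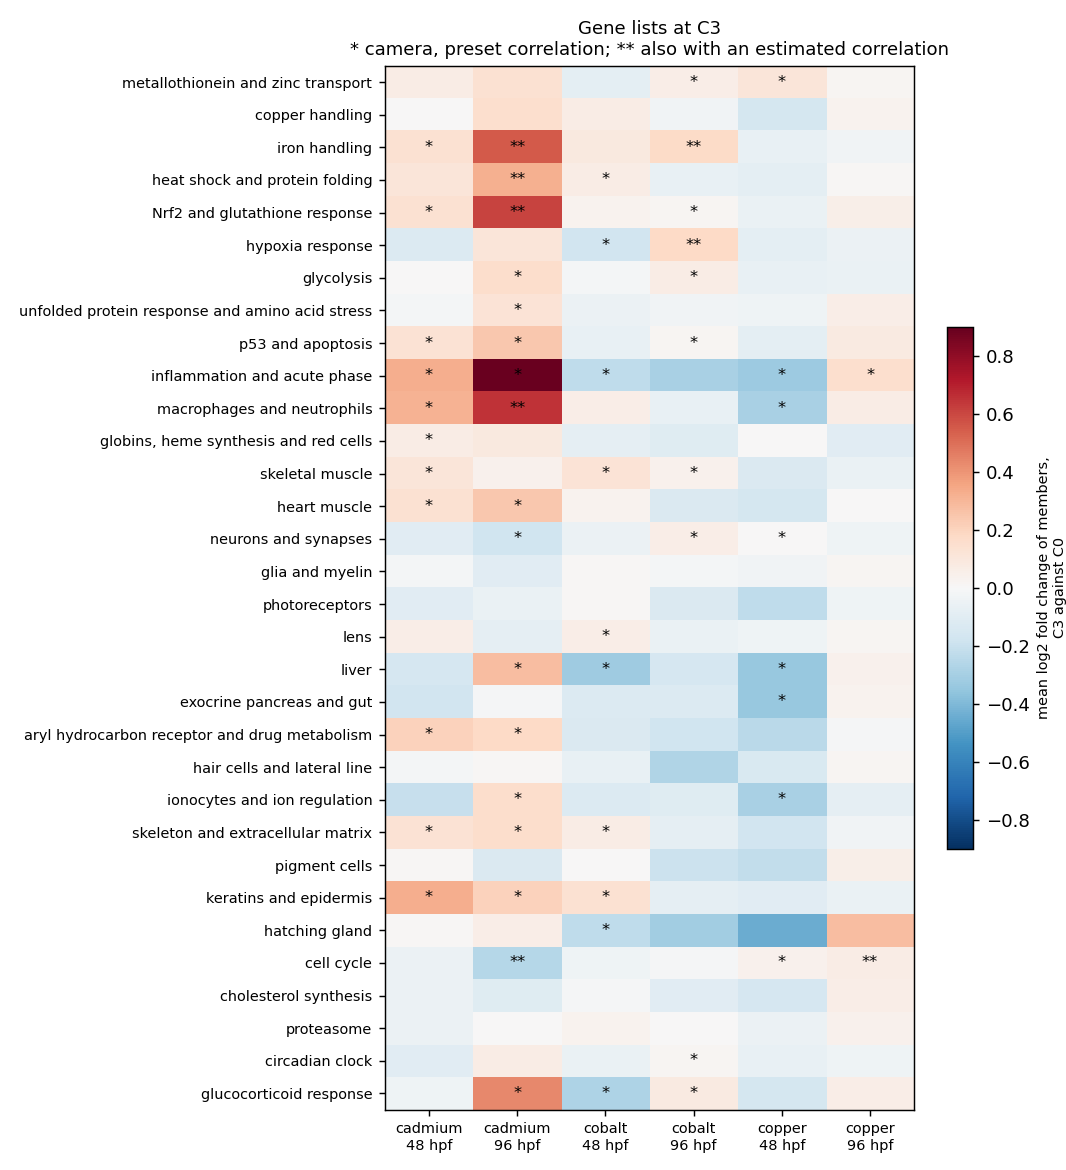
Heat map of the mean log2 change at C3 (colour) of 32 gene lists (vertical axis) in the 6 sets of metal and stage (horizontal axis); 1 star marks lists called by camera with a preset correlation and a pair of stars those called with an estimated correlation too. Inflammation at cadmium 96 hpf has the highest mean, 0.89.

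Single arrays moved the cadmium 96 hpf results. Without any 1 array other than control replicate 3, the count at C3 lay at 10 (without C3 replicate 1) to 19 (without C3 replicate 4), with 11 without control replicate 1 or 4, 15 without control replicate 2 and 17 without C3 replicate 2 or 3. hmox1a, hsp70l, pir and calml4b were called in each of these fits. mmp9 was not called without control replicate 4 (adjusted p = 0.0604) or C3 replicate 1 (0.0521), hsp70.3 not without these or control replicate 1 (0.0521 to 0.0665), and fthl31 not without 5 of the 8 arrays (up to 0.0772), namely control replicates 1, 2 and 4 and C3 replicates 1 and 2. mmp13a (up to 0.179), smtlb (up to 0.102), stat1b (up to 0.108), fthl29 (up to 0.195), sqstm1 (up to 0.291) and slc4a2a (up to 0.13) were called only with all arrays or without control replicate 3. slc30a1a was lost without each of the others except C3 replicate 2 (up to 0.102), and gsto2 without each except C3 replicate 4 (up to 0.206). The trend count was 15 without C3 replicate 1, 20 or 21 without control replicate 4 or 1, and 26, 27 and 26 without C3 replicates 2, 3 and 4. Glycolysis lost its call without control replicate 2 (0.204) or C3 replicate 3 (0.232), neurons without control replicate 1 (0.0608), skeleton and extracellular matrix without control replicate 1 or 4 or C3 replicate 2 or 4 (up to 0.145), and unfolded protein response without control replicate 2 or 4 or C3 replicate 2, 3 or 4 (up to 0.142). Hypoxia response gained one without control replicate 2 (0.0478) or C3 replicate 1 (0.0438), and pigment cells without control replicate 1 (0.0473).

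The next comparison asked whether the C3 response to a metal differed between stages. For cadmium it differed in 10 genes, all with a more positive change at 96 than at 48 hpf. The 96 hpf change minus the 48 hpf change was 3.26 ± 0.56 for hmox1a (adjusted p = 0.0248). It was 1.65 ± 0.31 for nfil3-6, a circadian and immune transcription factor (0.0455), and 1.32 ± 0.21 for tinagl1, a matrix protein (0.0112). The others were si:dkey-85k7.7, A_15_P513717, calml4b (0.0163), LOC100001838, LOC567822, A_15_P299476 and A_15_P300456. The last 5 had no array well above background in at least 1 of the 48 hpf groups, so the size of their difference was not measured. The changes at 48 and 96 hpf were −0.63 and 1.03 for nfil3-6 and −0.41 and 1.21 for si:dkey-85k7.7. Their differences thus held a negative change at 48 hpf too. After quantile normalization 5 genes differed, and after normexp correction 0. With the slide as a block 120 genes differed (96 higher, 24 lower), among them slc30a1a (1.02, 0.0109, and 0.369 without the block), smtlb (2.97, 0.0185), and stat1b and cd44a, not well above background on any 48 hpf array compared, on 1 side and the oxidase gene duox (−1.65, 0.0229) and kera (−1.13, 0.0279) on the other. Without control replicate 3 of 96 hpf 43 genes differed, or 309 with the block, and smtlb (3.44, 0.00169), stat1b (0.00094), slc30a1a (1.22, 0.0108) and sqstm1 (1.42, 0.0113) were among the 43. mt2 (1.46, adjusted p = 1, blocked 0.138) and hsp70l (0.78, 1 and 0.447) did not pass. The count was 3 without control replicate 3 of 48 hpf, and 4 without control replicate 1 of either stage or C3 replicate 1 of 48 hpf. It was 5 without C3 replicate 2 or 3 of 48 hpf or control replicate 4 or C3 replicate 1 of 96 hpf, and 6 without control replicate 2 or C3 replicate 2 of 96 hpf. The call of hmox1a was lost without 11 of the 14 arrays (adjusted p up to 0.11). That of calml4b was lost without any 48 hpf array except C3 replicate 2 and without 96 hpf control replicate 1 (up to 0.064), that of nfil3-6 without 12 of the 14 arrays (up to 0.237), and that of tinagl1 without 48 hpf control replicate 3 (0.0546). Those of A_15_P513717 (up to 0.141), LOC567822 (up to 0.138) and si:dkey-85k7.7 (up to 0.182) were lost without 10, 9 and 12 of the arrays. For cobalt limma called 0 genes (180 at an unadjusted p under 0.05), and 2 with the block, fkbp5 (1.80 ± 0.20, 0.00113) and lpin1a (1.72 ± 0.23, 0.011). For copper it called 0 with and without the block (343 at an unadjusted p under 0.05). Without control replicate 2 of 48 hpf 1 gene was called for each of these metals.

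For cobalt at 48 hpf no gene passed the test at any concentration. The genes with the smallest p at 3.6 mg/L were plxdc2a (at least 2.99-fold higher), cmpk2, a mitochondrial nucleotide kinase (at least 3.33-fold lower), fkbp5, a co-chaperone of the glucocorticoid receptor (−1.75 ± 0.33, SE, n = 3 against 3), agxtb, an alanine-glyoxylate aminotransferase (at least 1.5-fold lower), and stk35 (−0.90), each with an adjusted p of 1. Limma called 0 genes at C1, C2, C3 and for the trend, with and without the block. Without it 614, 87, 148 and 198 of 21430 features had an unadjusted p under 0.05, a smaller share than chance alone would give. The sentinels mt2 (0.00 ± 0.38), hmox1a (−0.39 ± 0.33), hsp70l (0.63 ± 0.49) and mmp9 (−0.01 ± 0.25) did not pass. In a fit of only C2 and C0 2 genes were called. Normexp correction moved the median change of all genes in this set to −0.267 at C3, and quantile normalization to −0.133 at C1, against −0.0113 and −0.012 in the main scaling.

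By list, liver genes ranked lower at cobalt 48 hpf (mean −0.32 over 46 genes, adjusted p = 2.24e-09, estimated 0.211). So did glucocorticoid response (−0.28, 3.09e-07, estimated 0.121), in which 1 of 30 members was lower adjusted over the list alone. Inflammation (−0.23, 1.75e-05; estimated 0.121), hypoxia response (−0.17, 0.000385; estimated 0.121) and hatching gland (−0.23, 0.00349; estimated 0.093) ranked lower too. Keratins (0.14, 2.66e-06), skeletal muscle (0.12, 5.25e-05), skeleton and extracellular matrix (0.07, 0.0116), heat shock (0.07, 0.0427) and lens (0.06, 0.0232) ranked higher, with an adjusted p of 0.49, 0.498, 0.453, 0.592 and 0.624 with an estimated correlation. No member of these lists passed over all genes. The test and the mean or median differed in sign for cholesterol synthesis and for macrophages and neutrophils, which did not pass. Calls were lost without 1 array for hypoxia (control replicate 3, 0.0875), lens (control replicate 3, C3 replicate 1 or 2, up to 0.544), heat shock (control replicate 1 or 2, C3 replicate 1 or 3, up to 0.262), skeletal muscle (C3 replicate 1 or 3, up to 0.0572) and extracellular matrix (control replicate 2 or C3 replicate 3, up to 0.455). Calls were gained by globins (control replicate 2 or C3 replicate 3, down to 0.00488), proteasome and macrophages (control replicate 3 or C3 replicate 2, down to 0.00228 and 0.0429), pancreas and gut (control replicate 2, 0.0325) and p53 (control replicate 1, 0.0369).

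Without the dim C1 replicate 2, 1 gene was called at each concentration, cmpk2 at C3 (at least 3.33-fold lower, adjusted p = 0.00318). The count was also 1 at each without control replicate 2, and 11 at C1 without C1 replicate 1. With the slide as a block and without C1 replicate 2, chosen after the data were seen, 1, 3 and 5 genes were called at C1, C2 and C3 and 4 for the trend. The 5 at C3 were lower, among them fkbp5, ca15a and cmpk2, named after their values were seen.

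At 96 hpf cobalt gave no call without the block, but with it ferritin heavy chain genes rose at all 3 concentrations. fthl28 was higher by 2.33 at 0.5 mg/L (adjusted p = 0.000381), by 2.51 at 1.4 mg/L (0.00018) and by 2.35 at 3.6 mg/L (0.000354), on each of the 4 slides. At C3 without the block its change was 2.35 ± 0.37 (SE, n = 4 against 4, adjusted p = 0.107), from 0.67 ± 0.60 (SD) in controls to 3.02 ± 0.76. fthl31 (1.16 ± 0.11 with the block, adjusted p = 0.00283, and 0.101 without), fthl29 (1.15 ± 0.12 on 3 slides, 0.00949 and 0.632, with 1.05 ± 0.20 without the block, n = 4 against 3) and zgc:173594 (1.37, 0.000964 and 0.107) rose with the block, and ca15a fell by 1.68 ± 0.20 on the log2 scale (0.0204 and 1). The probes of these ferritin genes and of zgc:173594 lie on chromosome 3 of danRer7 between 32242702 and 32277858, on the plus strand.

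The blocked counts for cobalt at 96 hpf were 4 at C1, 4 at C2, 5 at C3 (4 higher, 1 lower) and 3 for the trend. Without the block limma called 0 in each, with 277, 116, 415 and 167 genes at an unadjusted p under 0.05. At C1 fthl29 (1.01, 0.016) and fthl31 (0.95, 0.016), and at C2 fthl29 (1.1, 0.00726) and fthl31 (0.99, 0.0107), were called with the block. egln3, the prolyl hydroxylase that marks hypoxia signalling, had a change of 1.23 ± 0.46 at C3 (adjusted p = 1, blocked 0.643). rhcgb, an ammonia channel of ionocytes (−0.98, 0.632 and 0.0614), slc4a1b (−1.33, 0.632 and 0.26), mt2 (0.11), hmox1a (0.02) and hsp70l (0.09) did not pass. The sentinel hamp had a change of −1.20.

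Among the lists at cobalt 96 hpf, hypoxia response had a mean of 0.18 over 48 genes (adjusted p = 1.92e-08, estimated 0.0424) with 0 members called, 0 adjusted over the list alone and 0 with the block. Iron handling had a mean of 0.17 and a median of 0.01 over 20 genes (3.33e-05, estimated 0.0247), with 0 members called, 3 higher adjusted over the list alone and 3 with the block. Neurons and synapses (0.06, 4.69e-05), skeletal muscle (0.04, 0.000272), glucocorticoid response (0.08, 0.000901), glycolysis (0.07, 0.00241), circadian clock (0.02, 0.00338), Nrf2 and glutathione response (0.02, 0.00338), p53 and apoptosis (0.02, 0.00515) and metallothionein and zinc transport (0.06, 0.0301) ranked above the other genes. With an estimated correlation their adjusted p was 0.0708, 0.453, 0.182, 0.217, 0.123, 0.33, 0.234 and 0.121 in that order. The skeletal muscle list had the opposite direction after quantile normalization (adjusted p = 0.849), and so did keratins and epidermis (0.469, and 0.00794 after quantile normalization). Ionocytes had 3 members lower adjusted over the list alone and 1 with the block (adjusted p = 0.838). After normexp correction metallothionein (0.527), Nrf2 (0.0437), glycolysis (0.0318), p53 (0.36), skeletal muscle (0.000132), neurons (0.295) and glucocorticoid response (0.918) had the opposite direction. The median change of all genes at C3 was −0.0885, and it was 0.121 after normexp correction. The test pointed up where the mean or median did not for cell cycle, cholesterol synthesis, copper handling, pancreas and gut, glia, globins, heart muscle, heat shock, ionocytes, keratins, lens, macrophages, photoreceptors, extracellular matrix and unfolded protein response, none of which passed.

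Without 1 array, fthl28 was called at C3 (2.72, adjusted p = 0.0155, without C3 replicate 2), which made the count 1. Of the cobalt 96 hpf lists, circadian clock (0.174), skeletal muscle (0.768), Nrf2 (0.304), glycolysis (0.678), p53 (0.198) and metallothionein (0.304) lost their calls without control replicate 2, and glucocorticoid response (0.191), Nrf2 (0.0539), p53 (0.0566) and metallothionein (0.123) without C3 replicate 2. Nrf2 (0.138) and glycolysis (0.0531) lost theirs without C3 replicate 3, and metallothionein without control replicate 4 (0.0879) or C3 replicate 1 (0.0859). Calls were gained by cell cycle without control replicate 1, 3 or 4 or C3 replicate 4 (0.00225 to 0.0456), by proteasome without control replicate 3 or 4 or C3 replicate 1 or 4 (0.00181 to 0.0306) and by lens without control replicate 4 (0.00776) or C3 replicate 2 (0.00967). Copper handling gained one without control replicate 4 (0.0427), pancreas and gut (0.0139) and keratins (0.0186) without C3 replicate 1, and inflammation without C3 replicate 3 (0.00688). With the block and without control replicate 2, chosen after the data were seen, 2, 5 and 7 genes were called at C1, C2 and C3 and 2 for the trend.

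Copper at 48 hpf gave no call without the block at any concentration. cyp2x10.2, a cytochrome P450, had the smallest p at 6.1 µg/L (−1.55 ± 0.22, SE, n = 3 against 3, adjusted p = 0.307, blocked 0.108), and at 2.5 µg/L it was lower with the block (−1.78, 0.0439, and 0.18 without). LOC101884293 was lower with the block at C2 (−1.38, adjusted p = 0.0439) and at C3 (at least 1.74-fold, 0.0119, and 0.931 without). The next at C3 were dnal4a, a dynein light chain (at least 3.62-fold lower, 0.512), trim35-34 (at least 2.49-fold lower, 0.512), nitr6a, an immune-type receptor (at least 2.56-fold lower, 0.598), and pkib, a kinase inhibitor (−0.63 ± 0.13, 0.701). Limma called 0 genes at C1, C2, C3 and for the trend, with 466, 589, 854 and 633 at an unadjusted p under 0.05, and 0, 2, 1 and 1 with the block. Without the filter on dim probes 1 gene was called at C2 and 1 at C3. The copper exporter gene atp7a (−1.14), the copper importer gene slc31a1 (0.17), mt2 (0.17) and egln3 (0.79) did not pass at C3, nor did egln3 at C2 (1.26 ± 0.29, 1 and 0.57).

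Liver genes ranked lower at copper 48 hpf (mean −0.34, adjusted p = 0.000385; adjusted p = 0.49 with an estimated correlation), with pancreas and gut (−0.34, 0.00515; estimated 0.514), inflammation (−0.33, 0.00435; estimated 0.548), macrophages and neutrophils (−0.29, 0.000198; estimated 0.156) and ionocytes (−0.29, 0.0298; estimated 0.548, blocked 0.0832). Metallothionein and zinc transport (0.11, 0.00116; estimated 0.0651), cell cycle (0.04, 0.000649; estimated 0.49) and neurons (mean 0.00, 0.0464; estimated 0.624, blocked 0.0652) ranked higher. No member of these lists passed over all genes, adjusted over the list alone, or with the block. Lens (0.052), pigment cells (0.0524), skeletal muscle (0.0785) and photoreceptors (0.0785) passed with the block only (0.0253, 0.0266, 0.0495 and 0.0464). There 0 passed with an estimated correlation. The sign of the test differed from that of mean or median for circadian clock, glia, globins, heat shock, hypoxia, iron handling, lens, p53, proteasome and unfolded protein response, none of which passed without the block. Without control replicate 2 cell cycle turned (0.54), and metallothionein (0.098), pancreas and gut (0.178) and neurons (0.0633) lost their calls. Without control replicate 3 liver (0.677), inflammation (0.959), macrophages (0.149), ionocytes (0.778), pancreas and gut (0.184) and neurons (0.43) did. Without C3 replicate 1 inflammation (0.27), ionocytes (0.0595), pancreas and gut (0.128) and neurons (0.0987) lost theirs, without C3 replicate 2 ionocytes (0.158), and without C3 replicate 3 neurons (0.237). A call was gained without at least 1 array by 15 other lists, with the smallest adjusted p for skeletal muscle (0.00095 without C3 replicate 1), keratins (0.00103) and Nrf2 (0.00182), both without control replicate 2. Single genes were called without 1 array, at most 2 at C1 and 4 at C2 (without control replicate 1) and 5 at C3 (without control replicate 3), with dnal4a among the last (0.0367). The trend had 1 without control replicate 1, where nitr6a was called at C3 (0.0109) as 1 of 2 genes, and without control replicate 3 the counts at C1 and C2 were 1 and 2.

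At 96 hpf copper gave no call in any fit, with or without the block and with any 1 array left out. The smallest p-values at 6.1 µg/L were those of ankef1a (1.64 ± 0.38, SE, n = 4 against 4), the interferon-induced gene family member ifi44f5 (1.31 ± 0.33), the nucleoside transporter slc28a1 (−2.14 ± 0.56), the transcription factor npas1 (−0.82 ± 0.22) and baiap2l2b (−1.15 ± 0.32), each with an adjusted p of 1 and of 0.959 with the block. At C1, C2, C3 and for the trend 315, 126, 146 and 179 genes had an unadjusted p under 0.05. mt2 (0.19), slc31a1 (−0.18) and atp7a (0.15) did not pass. Cell cycle genes ranked higher (mean 0.07 over 62 genes, adjusted p = 0.00544, estimated 0.0448). So did inflammation (0.15, 0.00163, estimated 0.548), with 0 members called in either. With the block globins (0.0291), skeletal muscle (0.04) and cholesterol synthesis (0.0412) passed as well, against 0.0561, 0.0641 and 0.0586 without. With block and estimated correlation 0 of the 192 list tests passed. Cell cycle lost its call without control replicate 2 (0.107) or 4 (0.0585) or C3 replicate 4 (0.0575), and inflammation without control replicate 1 (0.283) or C3 replicate 3 (0.106) or 4 (0.0659). A call was gained without at least 1 array by 11 other lists, with the smallest adjusted p for keratins (0.00103), globins (0.00156) and extracellular matrix (0.00266), each without C3 replicate 4. Mean and median differed in sign for the glia list, which did not pass.

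The C3 responses of the sentinel genes were compared between metals, and 20 of 114 differences passed, and 27 with the block. At 96 hpf the cadmium change exceeded that of cobalt and of copper for mmp9 (by 4.72 ± 0.91, adjusted p = 0.000122, and by 4.24, 0.000438), hmox1a (3.36 ± 0.52, 1.15e-05, and 3.21, 1.44e-05), hsp70l (2.41 ± 0.45, 9.93e-05, and 2.27, 0.000154), mt2 (2.38 ± 0.57, 0.00163, and 2.3, 0.00223), slc30a1a (1.13 ± 0.21, 0.000104, and 1.17, 9.93e-05) and sqstm1 (1.29 ± 0.35, 0.00579, and 1.66, 0.000279). It exceeded that of cobalt for fosl1a, a wound response transcription factor (4.60 ± 1.41, 0.0147), and hamp (2.99 ± 0.84, 0.00713). A part of each gap lay in cobalt, where fosl1a changed by −1.92 and hamp by −1.2, neither called. The cadmium change did not differ from that of copper for either without the block (0.385 and 0.242). Without control replicate 2 of cobalt at 96 hpf, whose median correlation with its group was 0.796, 18 differences passed. For egln3 the cobalt change exceeded that of copper at 96 hpf (1.52 ± 0.53, 0.0412), while at 48 hpf it was below it (−1.30 ± 0.45, 0.0432), as was that of cadmium (−1.64 ± 0.45, 0.00759). At 48 hpf the cadmium change of mmp9 exceeded that of cobalt (2.00 ± 0.49, 0.0032) and copper (2.17, 0.00163), and that of hsp70l exceeded copper's (1.90 ± 0.49, 0.0048). The 7 differences that passed only with the block were, at 48 hpf, mt2 (1.03, adjusted p = 0.0434 with the block and 0.141 without) and hsp70l (1.1, 0.0493 and 0.141) for cadmium minus cobalt and sqstm1 (0.79, 0.0192 and 0.0756) for cadmium minus copper. At 96 hpf they were il1b (3.81, 0.0176 and 0.0641) and egln3 (−1.32, 0.0423 and 0.0873) for cadmium minus cobalt, and hamp (1.59, 0.0368 and 0.242) and gclm (0.56, 0.0493 and 0.141) for cadmium minus copper. The il1b gap also held a change of −1.51 in cobalt.

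No gene was called in the same direction for any pair of metals at C3 without the block. With the block cadmium and cobalt at 96 hpf shared 4 higher genes, fthl28, fthl29, fthl31 and zgc:173594, of 22544 tested in both, where independent lists would share 0.0777 (one-sided Fisher's exact test, p = 1.41e-07). Without control replicate 3 of cadmium, chosen after the data were seen, they shared 5. The metals had separate controls, and genes are not independent of each other in this test. No gene was shared by all 3 metals.

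**Figure D4:**
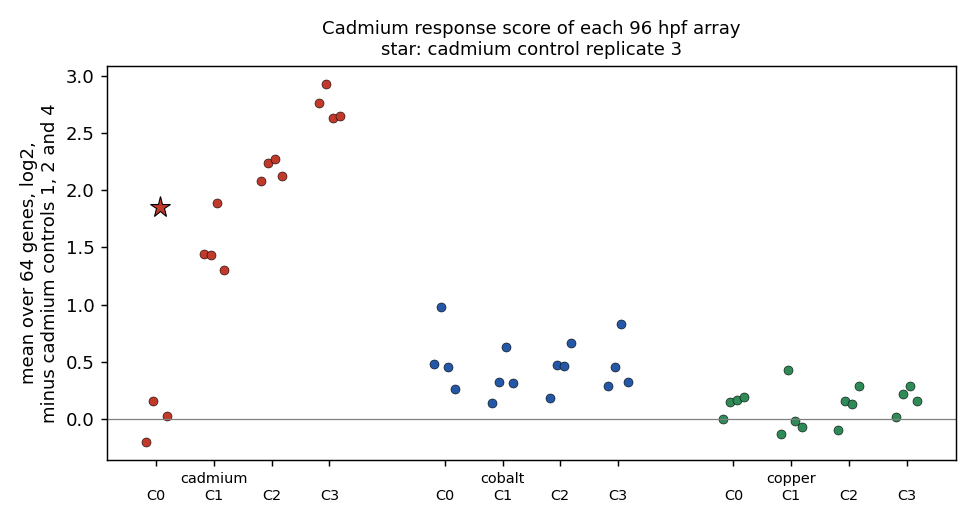
Score of each 96 hpf array (vertical axis, mean log2 difference from the other 3 cadmium controls over 64 genes that responded on the other slides, signed by their direction) by metal and concentration group (horizontal axis), with 1 point per array. Control replicate 3 of cadmium has 1.85, above all 8 cobalt and copper controls, which lie at 0 to 0.98.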

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

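The tests on control replicate 3 of cadmium at 96 hpf and on the position of arrays on a slide were chosen after the results were seen. The counts of other splits of the samples were planned.

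Control replicate 3 of cadmium at 96 hpf carried the cadmium response. Its score over 64 genes that responded on the other slides was 1.85, against −0.20 to 0.16 in the other cadmium controls, 0 to 0.98 in the 8 cobalt and copper controls, and 1.3 to 2.93 in the 12 exposed cadmium arrays. An exchange of labels with an exposed array of its own slide is argued against, since the lowest of those 3 arrays scored 1.89, and so is a shift of the whole slide, since these arrays exceeded their group mates by only 0.16. At C1, C2 and C3 they scored 1.89, 2.27 and 2.63, against means of 1.39, 2.15 and 2.78 on the other slides. The genes were called on those other slides, so the scores of their controls and C3 arrays are not independent of that choice. The value of 1.85 is consistent with RNA of exposed embryos in that tube, or with control embryos that met cadmium. A wrong tube and a real exposure of that control may both account for it, and no value here separates them.

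Each slide carried C0 to C3 in a fixed order, so the position on the slide could mimic an effect of concentration. Cobalt and copper used the same positions. The genes called for cadmium at C3, signed as in cadmium, had a median change at 48 hpf of 1.72 in cadmium, 0.32 in cobalt and 0.02 in copper. At 96 hpf the medians were 2.41, −0.02 and 0.01. The genes that rose with cobalt at 96 hpf changed by a mean of 1.44 in cobalt and −0.06 in copper. With the block they also rose with cadmium at 96 hpf, in the same positions, so for them only copper tests position. Position alone is argued against for these 3 responses, and that they come from the metals stays a hypothesis.

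Among the named genes, 1 array lay far from the other 3 of its 96 hpf group for 4, 14, 12 and 9 genes in cadmium C0 to C3, for 7, 11, 7 and 6 in cobalt and for 8, 2, 6 and 9 in copper, of at most 96 genes tested per group. Chance marks about 1 in 20 groups. Replicate 2 stood apart by its lower percent of probes well above background in cadmium C0 (69.35) and C2 (70.24), cobalt C1 (68.83) and C3 (68.23) and copper C1 (69.99). The cadmium arrays of replicate 2 had a multiplier of 2.6 for this flag, against 13 on the other arrays. The same replicate stood apart by a lower median correlation with its group in cadmium C0 to C3 (0.9325, 0.9331, 0.9357 and 0.9323), in cobalt C0 (0.796), C1 (0.9449) and C3 (0.9397), and in copper C1 to C3 (0.9198, 0.9466 and 0.9502).

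The C3 response to cadmium differed between 48 and 96 hpf, by limma's test of the difference itself, in 10 genes. On the log2 scale the change at 96 hpf exceeded that at 48 hpf by 3.26 for hmox1a, 3.25 for A_15_P513717, 1.65 for nfil3-6, 1.62 for si:dkey-85k7.7 and 1.32 for tinagl1, with A_15_P513717 well above background on 1 of 3 arrays in each 48 hpf group. For the other 5 at least 1 of the 48 hpf groups had no array well above background, so the computed differences of 4.84 for A_15_P300456, 3.52 for A_15_P299476, 3.3 for calml4b, 2.92 for LOC567822 and 1.82 for LOC100001838 rest on values near the floor and are not measured sizes.

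Other splits of the same arrays showed which counts chance can give. For cadmium at 96 hpf and C3, 1 of 35 splits, the real one, gave as many as 43 genes, and the highest other gave 3. That share is under 0.05, so chance is unlikely, but it was not adjusted over the tests run. In the fit with the slide as a block, the real split gave 707 genes and the 7 others that part every pair at most 1. For the cadmium 96 hpf trend 2 of 100 draws gave as many as the real 44 (highest other 3333), for the stage difference of cadmium 4 of 100 gave as many as 10 (highest other 58), and for the sentinels between metals 1 of 100 gave as many as 20 (highest other 14). The shares of these 3 were under 0.05 as well, also without adjustment over the tests, so chance is unlikely but not excluded. For the cadmium 48 hpf trend 8 of 100 draws gave as many as 8 genes (highest other 7215). These draws ignored the slides and leave chance open for that trend.

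The trend draws that called many genes followed the slides. In the draw with 7215 genes 82.6% of the trend weight lay between slides, with 51.7% in that with 3333 genes, 76.7% in the cobalt 48 hpf draw with 1044, 71.8% in the copper 48 hpf draw with 3068 and 46.9% in the copper 96 hpf draw with 2284. The real trends had 0% between slides, and with the slide as a block the real counts were 62 for cadmium at 48 hpf, 839 for cadmium at 96 hpf, and 0, 1 and 0 for the other 3 sets in that order.

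The 10 splits of 3 against 3 arrays were too few for a share under 0.05. For cadmium at 48 hpf 1 of 10 gave as many as the real 3, 9 and 9 genes at C1, C2 and C3 (highest other 1 each), and with the block the real counts were 197, 115 and 105 against 1 in the other splits that part every pair. For cobalt and copper at 48 hpf the real counts were 0, and 10 of 10 splits reached them, with a highest other of 1, 1 and 0 for cobalt and 1, 2 and 2 for copper. List counts in the splits were adjusted over the 32 lists of a set, which called 13, 10 and 7 lists at 48 hpf and 18, 10 and 2 at 96 hpf for cadmium, cobalt and copper, where the adjustment over all 192 tests used in the results called 11, 10 and 8, and 17, 10 and 2. At 48 hpf, 1 of 10 splits reached the real 13 for cadmium (highest other 11), 1 of 10 the real 10 for cobalt (highest other 7) and 8 of 10 the real 7 for copper (highest other 16). At 96 hpf chance cannot be excluded for the number of lists called: 3 of 35 splits reached 18 for cadmium (highest other 22), 11 of 35 reached 10 for cobalt (21) and 15 of 35 reached 2 for copper (16). Among the 8 splits that part every pair the highest other was 16 for cadmium, below the real 18, so the 2 other splits that reached 18 left array pairs of a slide together, and 8 splits are too few to exclude chance. For cobalt and copper those highest others were 15 and 5, above the real 10 and 2. At 48 hpf, among 4 such splits, they were 11, 4 and 9 for cadmium, cobalt and copper.

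For the remaining real counts of 0, every split gave as many. This held for 35 of 35 splits at cadmium 96 hpf C1 and C2 (highest others 1 and 0), cobalt 96 hpf C1, C2 and C3 (1, 0 and 1) and copper 96 hpf (1 each). With the block the real counts were 19 at cadmium 96 hpf C2 and 4, 4 and 5 at cobalt 96 hpf, against at most 0 in the other splits that part every pair. It held for 100 of 100 draws in the trends of cobalt at both stages (1044 and 1) and of copper at both stages, in the stage differences of cobalt (1) and copper (1370), and in the 6 overlaps between metals (0 each).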

How the results depend on the processing

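The probes well above background, 66.8% in copper 96 hpf C0 replicate 2 to 92.4% in copper 48 hpf C0 replicate 2, limited what could be called, and the 13 lowest shares, up to 73.75%, were those of replicate 2 at 96 hpf and of cobalt 48 hpf C1 replicate 2. Counts of 0 in cobalt and copper may therefore miss changes in weakly expressed genes and moderate changes at any expression level. Without a block, 0% to 18.2% of simulated 2-fold changes were recovered in these sets. The shares of cadmium replicate 2 at 96 hpf were counted with the lower multiplier of 2.6. Leaving 1 array out takes samples from the test, which by itself can lower a count.

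The series matrix held the same processed signal, apart from rounding and a factor of 1 or about 1000000 per array, so refitting it tested nothing and its values are not counted below. The mean of all probes and rank weights for concentration kept every count within 1.5 times, as did quantile normalization except for the stage difference of cadmium (10 genes to 5). Over the other alternatives, named genes called with all arrays kept the call in 259 of 477 values, lost it in 215 and turned direction in 3, and those not called gained a call in 241 of 6156. Lists called kept the call in 689 of 1044 values, lost it in 345 and turned in 10, and those not called gained one in 152 of 2412 and turned in 28. Stage differences of named genes kept their call in 124 of 200 values and gained one in 31 of 1261, and sentinels between metals kept theirs in 112 of 120 and gained one in 16 of 564.

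After normexp background correction the counts for cadmium at 48 hpf fell from 3, 9 and 9 genes to 0, 0 and 0 at C1, C2 and C3, and from 8 to 0 for the trend. Cadmium at 96 hpf fell from 43 to 0 genes at C3 and from 44 to 3 for the trend, the stage difference of cadmium from 10 to 0, and the lists called rose from 58 to 101. Turned in direction were A_15_P113609 (−0.31 at C2) and LOC571582 (−0.17 at C2, −0.24 at C3) at cadmium 48 hpf. The cause was not tested. Without the filter on dim probes more genes were tested, and the counts were 5 at cadmium 48 hpf C1 (from 3), 28 at cadmium 96 hpf C3 (from 43) and 1 and 1 at copper 48 hpf C2 and C3 (from 0). A fit on only the compared groups, with fewer samples, gave 1, 1 and 0 genes at cadmium 48 hpf C1 to C3, 1 gene at cadmium 96 hpf C3 and 2 genes at cobalt 48 hpf C2.

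Lists that turned in direction after normexp correction had these adjusted p values. At cadmium 48 hpf they were cell cycle (4.45e-07) and proteasome (1.76e-07), and at cadmium 96 hpf neurons and synapses (0.665), glia and myelin (0.0426), photoreceptors (0.0362) and lens (0.00191). At cobalt 48 hpf they were glycolysis (0.000393), unfolded protein response (0.0011) and cell cycle (7.95e-07). At cobalt 96 hpf they were metallothionein (0.527), heat shock (0.00686), Nrf2 (0.0437), glycolysis (0.0318), unfolded protein response (6.25e-06), p53 (0.36), skeletal muscle (0.000132), neurons (0.295), glia (0.0164), photoreceptors (8.57e-05), lens (0.000359), ionocytes (0.022), extracellular matrix (0.00128), keratins (2.15e-06), cell cycle (1.88e-05), proteasome (9.44e-06) and glucocorticoid response (0.918). At copper 96 hpf they were glycolysis (0.000172), skeletal muscle (3.76e-07), neurons (0.00146), photoreceptors (0.000122), extracellular matrix (0.0011), keratins (6.62e-05) and circadian clock (0.0113). After quantile normalization skeletal muscle (0.849) and keratins (0.00794) turned at cobalt 96 hpf. Without copper 48 hpf C0 replicate 2, unfolded protein response (0.0334), cell cycle (0.54) and proteasome (0.000852) turned at copper 48 hpf. Over all arrays left out in turn, the adjusted p there ran from 0.00251 to 0.962, from 3.91e-06 to 0.54 and from 0.000852 to 0.453. The cause was not tested.

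Of the 58 lists called with the preset correlation, 8 remained with an estimated correlation between genes. Limma's fry, which tests a list against no change rather than against the other genes, called 5 of the 58. With the estimated correlation and without cadmium 96 hpf C0 replicate 3, a choice made after seeing the data, 9 lists were called. With the replicate block 65 lists were called with the preset correlation. In that blocked fit 0 were called with an estimated correlation and 27 with fry, combinations also chosen after seeing the data. The cause was not tested.

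The replicate number as a block, the same fit as slide or scan day as a block, raised cadmium at 48 hpf to 197, 115 and 105 genes at C1 to C3 and 62 for the trend, and cadmium at 96 hpf to 19 genes at C2, 707 at C3 and 839 for the trend. It gave cobalt at 96 hpf 4, 4 and 5 genes and 3 for the trend, and copper at 48 hpf 2 genes at C2, 1 at C3 and 1 for the trend. Stage differences rose to 120 genes for cadmium and 2 for cobalt, and the genes shared by cadmium and cobalt at 96 hpf to 4. The block moved no other count of calls by over 1.5 times. Alternatives chosen after seeing the data left out 1 array in the blocked fit. Without C0 replicate 3, cadmium at 96 hpf had 89, 458 and 1066 genes and 1185 for the trend, a stage difference of 309 genes and 5 genes shared with cobalt. Without C0 replicate 2, cobalt at 96 hpf had 2, 5 and 7 genes and 2 for the trend. Without C1 replicate 2, cobalt at 48 hpf had 1, 3 and 5 genes and 4 for the trend. The cause was not tested.

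Leaving each array out in turn, with the spread pooled over the 4 groups, gave for cadmium at 48 hpf 1 to 4 genes at C1, 3 to 5 at C2, 4 to 12 at C3 and 3 to 9 for the trend. For cadmium at 96 hpf it gave 0 to 18 at C1, 0 to 71 at C2, 10 to 128 at C3 and 15 to 136 for the trend. Cobalt at 48 hpf had 0 to 11 at C1, 0 to 1 at C2, 0 to 1 at C3 and 0 for the trend, and at 96 hpf 0 to 1 at C3 and 0 at C1, C2 and for the trend. Copper at 48 hpf had 0 to 2 at C1, 0 to 4 at C2, 0 to 5 at C3 and 0 to 1 for the trend, and at 96 hpf 0 throughout. Overlaps between metals stayed at 0. Stage differences were 3 to 43 genes for cadmium, 0 to 1 for cobalt and 0 to 1 for copper. The lists called were 51 to 65, and the sentinels between metals 18 to 22.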

Other observations

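The tests of slower development were planned, and the calls with the slide as a block that follow were planned as an alternative. The genes named in the next 2 paragraphs were taken by the rule applied to the blocked fit, after the data were seen.

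In the fit with the slide as a block, further single genes were called for cadmium at 3.3 mg/L and 96 hpf. In the pigment cell list, which did not pass (adjusted p = 0.186), pmelb, a melanosome fibril protein (−0.72, adjusted p = 0.0315), gch2, of pteridine synthesis (−0.68, 0.0305), and mitfa, the regulator of melanophore fate (−0.48, 0.0351), were lower, as the only 3 of 35 tested members called. The heart genes myh7l (0.86), myh6 (0.74), both cardiac myosins, and nppa (0.73), the natriuretic peptide A gene, were higher, as 3 of the 4 of 22 tested heart genes called. The potassium channel gene kcnj1a.2 (−2.19, 0.0352), the growth factor binding protein gene igfbp5a (−1.15, 0.012) and the sterol synthesis gene lss (−1.03, 0.0232) were lower, while prl, prolactin (1.84, 0.0323), igfbp1b (1.45, 0.014) and the fibronectin gene fn1b (1.32, 0.00569) were higher. Without the block none of these passed with all controls, and igfbp1b (1.75, adjusted p = 0.035) and fn1b (1.5, 0.0418) passed without control replicate 3.

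At 48 hpf the genes called for cadmium at C3 in the blocked fit included the neutrophil peroxidase gene mpx (0.73, adjusted p = 0.0209), anxa1b (0.90, 0.00543), gadd45bb of the growth arrest response (1.15, 0.0228), the prostaglandin synthase gene ptgs2a (0.73, 0.0426) and evplb, an epidermal envelope protein (0.68, 0.0228). The glucocorticoid target klf9 (−1.05, 0.0339) was lower. The fin fold genes and3 and and1 were already higher at C1 (2.16, 0.0332, and 1.46, 0.0227).

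A hypothesis was that the cadmium response at 96 hpf came from slower development. Genes lower in exposed embryos would then rise with age, and genes higher would fall with age, in the cobalt and copper controls. Of the 254 lower genes 34.3% rose from 48 to 96 hpf, against 53.3% of all tested genes, and of the 453 higher genes 21% fell, against 46.7%. Both shares lay below those of all genes, so slower development is argued against as the source of either group as a whole. A rise of over 2-fold with age was seen in 17.7% of the lower genes, against 15.4% of all tested genes, so a part of the lower genes stays open, and a fall of over 2-fold in 3.3% of the higher genes, against 5.8%. The median change with age was −0.56 for the lower genes and 0.61 for the higher genes.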
